A study of Escherichia coli
Bacillus subtilis with 2 samples.

How the data were processed

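The 2 NET-seq libraries of wild-type *E. coli* analysed here, 1 with and 1 without apyrase, were grouped by their titles. Per the labels' protocols, cells were filtered and frozen in liquid nitrogen, ground together with *B. subtilis* spike-in cells, treated with DNase on ice, with 15 units of apyrase added at that step in 1 library, and quenched with EDTA. RNA polymerase was then bound through its FLAG tag, its RNA was ligated to an adaptor at the 3′ end and sequenced. The labels speak of triplicate cultures per strain, of which 1 library per condition was used here.

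Per the file headers, each of the 2 deposited files gives, for every position and strand of 1 chromosome, 4 values. The count of 3′ ends deposited by the authors is a raw whole number and was the basis of all results. The coverage signal deposited beside it was checked on the values: it equals 15 nt per read at every position, so the read body carries no length information. The deposited fraction is that count over that coverage. The score that the authors deposited as normalized 3′ reads equals the count times 1 factor per library, 1.5432 without and 1.3072 with apyrase, rounded down. What the factors were derived from is not given in the sources used here, and they served as an alternative scaling only. The submitters' processing notes name R 4.1.0, cutadapt, Bowtie, SAMtools and bedtools without roles. The genome build, the filters and the handling of reads that match several places are not given in the sources used here. Counts of *B. subtilis* and its genome were not used here, nor was a genome sequence of *E. coli*.

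Gene names and boundaries came from a RefSeq gene table of assembly ASM584v2 with 4651 genes. Whether the files use the same coordinates was checked on the data. Stretches of at least 100 nt without any count on either strand in both libraries numbered 8, 7 holding ribosomal RNA and 1 ssrS, and 11 of their 16 edges fell exactly on an annotated gene end, the others within 5 nt. In each library, 43 of 72 tRNA genes with counts had their top 3′ end exactly on the annotated end; the other 29 held 0 counts within 3 nt of it, for a reason the files do not give, and stay out of the tests of tRNA ends. The table gives no strand, so a gene's strand was taken from the counts: the strand with at least 66.7% of the counts of both libraries. This assigned 1995 of 4290 protein-coding genes and left out 2295, and all 116 assigned genes among 126 with a strand known beforehand matched. Genes with counts spread over both strands therefore stay out of the gene results. The 2 near-identical tuf genes both held counts, so their values are uncertain. Positions are printed as the files give them.

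Sense counts per gene were scaled to the sum over assigned protein-coding genes. Genes with at least 100 counts in each library were compared as log2 of apyrase over untreated, with exact binomial 95% intervals of the count ratio. No test across libraries exists with 1 library per condition, so genes are named by size. Named were the 12 highest and 12 lowest genes, from each fixed list the 2 members with most counts and the member with the largest ratio, all leader peptides, and the 4 pause sites with most counts of each register class. In total 19 gene lists were fixed before the data were examined (ribosomal proteins, RNA polymerase and elongation factors, ATP synthase, purine synthesis, pyrimidine synthesis, salvage, leader peptides, amino acid biosynthesis under attenuation, aminoacyl-tRNA synthetases, translation factors, heat shock, cold shock, SOS, stationary phase, flagella, glycolysis, TCA cycle, outer membrane proteins and stable RNAs), along with most tests and most alternatives. A list's median was placed among 10000 random lists matched on density in 10 classes. Position along genes used the first and last 100 nt of genes of at least 500 nt.

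A pause site was a position with at least 20 counts that stood over 4 SD above the mean of the 100 nt on each side, with a window mean of at least 1, outside stable RNA genes and 20 nt around them. The apyrase library was thinned at random to the 16727460 counts of the untreated library there, which kept 93.7% of it; an added alternative thinned each strand of the genes to equal counts. Chance sharing was the mean overlap after shifts of 20 to 50 nt. For the register, sites were called on the sum of both thinned libraries, weaker sites within 5 nt of a higher one were left out, and the top position within 3 nt was compared between libraries with at least 20 counts in each window; 17 sites with unresolved ties were left out. Upstream and downstream follow the direction of transcription on the strand of the site.

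The steps were tested on simulated values. Of 200 genes changed among 1987, all those changed 3-fold were called at the 2-fold threshold, 0% of those changed 1.5-fold and 0 unchanged genes. Of 1828 simulated pause sites moved by 1 nt, 1237 were measured, and 98.9% of those measured were recovered. Only strong sites were moved, and each swapped its counts with the neighbouring nucleotide. Recovery of partial shifts or of weak sites was therefore not tested. Without any movement the upstream to downstream ratio of 1-nt shifts was 0.936. Among 200 random gene lists, 6.5% fell outside the central 95%. Their log2 ratios were simulated independently for each gene, without a trend with density or ties within operons. The percentiles of the real lists may be less well calibrated. Planned measures that need a genome sequence (bases at pause sites and at 3′ ends, the profile at consensus sites, ops elements) or *B. subtilis* counts (spike-in ratio and scaling, spike-in register) were not run. Alternatives covered the scaling, count minimum, strand rule, threshold, window, thinning and the leaving out of the highest position per gene. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.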

Results

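Nascent elongating transcript sequencing (NET-seq) reads the RNA that is still held by RNA polymerase. The 3′ end of each RNA is the last nucleotide the enzyme added, so a count at a position can mark a polymerase halted there, though mature RNA and background are counted too. The *E. coli* cells carried a FLAG tag on the β′ subunit (rpoC), through which polymerase was pulled out of the lysate, and *B. subtilis* cells with the same kind of tag were mixed in as a spike-in. Cells were harvested in early log phase from rich defined medium with glucose. A lysate received apyrase, an enzyme that breaks down nucleoside triphosphates, together with the DNase after the cells were broken open, and another did not. Each condition had 1 library, named here the untreated and the apyrase library. The differences below therefore have no replicate check. Intervals cover either counting error or the spread over genes, sites or stretches of the genome, and none covers variation between libraries. Reads need not be independent molecules, so counting intervals may be too narrow. The untreated library held 18011232 *E. coli* 3′ ends and the apyrase library 19724460, and 49.4% and 41% of strand positions had at least 1 end.

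The series title states that pause registers differ with apyrase, and the first comparison addressed that point. At most pause sites the position with most 3′ ends was the same nucleotide in both libraries, and where it differed it lay most often 1 nt upstream with apyrase. Of 31970 sites called on the sum of both libraries, 89.5% (95% exact interval 89.2 to 89.9) had the same top nucleotide, 6.96% (6.68 to 7.24) moved upstream and 3.52% (3.32 to 3.73) moved downstream. A site between ygcW and yqcE had 52.0% (50.2 to 53.9) of its 2881 untreated ends at position 2900556 of the plus strand, whereas 53.4% (52.3 to 54.6) of its 7814 apyrase ends lay at 2900555. On the minus strand 40 nt upstream of the yrbN coding sequence, position 3307973 held 82.9% of the untreated ends and 31.2% of the apyrase ends, and 3307974, which is 1 nt upstream, held 10.6% and 54.6%. Within the boundaries of fnrS, a small RNA gene of the FNR regulon matched by position only, the top was 1409183 without apyrase and 1409182 with it. In fau, near nucleotide 20 of the coding sequence, the top moved by 3 nt, from 3056263 to 3056260.

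The direction was carried by shifts of 1 nt. The top nucleotide was 1 nt upstream at 1331 sites and 1 nt downstream at 301, a ratio of 4.42 (3.90 to 5.03), whereas shifts of 2 nt were at 576 and 540 sites and shifts of 3 nt at 317 and 281. Random splits of a single library into 2 equal parts gave ratios of 0.924 (0.732 to 1.16) for the untreated and 0.991 (0.815 to 1.2) for the apyrase library, with 95.8% and 95.3% of sites at the same nucleotide. One part of each library set against the other library's gave 3.91 (3.24 to 4.76). On average over sites, the nucleotide just upstream of the top position held 7.14% of the untreated and 10.6% of the apyrase ends, the nucleotide just downstream 7.39% and 5.50%, and the top position 60.6% and 60.1%. The median shift of the count centroid was -0.0617 nt (-0.0659 to -0.0573, 95% interval of the median from ranked sites). At mature tRNA 3′ ends, in 42 tRNA genes with at least 100 counts in each library, the nucleotide 1 nt upstream held a mean of 1.22% of the untreated and 1.21% of the apyrase ends, a difference of -0.0077 percentage points (-0.060 to 0.041, resampling genes).

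**Figure D1:**
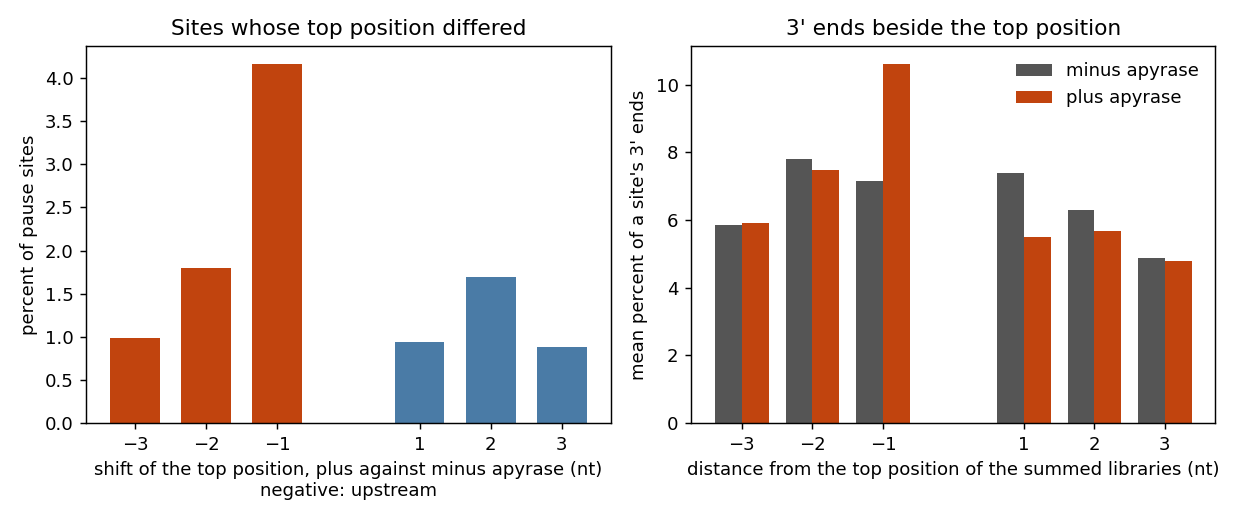
Left, percent of 31970 pause sites (y axis) by the distance in nt between the top positions of the 2 libraries (x axis, negative is upstream with apyrase); sites with the same top nucleotide, 89.5%, are not drawn. Right, mean percent of a site's 3′ ends (y axis) at each distance in nt from the top position of the summed libraries (x axis) for the untreated (grey) and the apyrase library (orange): the bar just upstream stands at 7.14% and 10.6%, and the top position itself is not drawn.

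Strong sites often kept their nucleotide. The highest lay within the boundaries of the small RNA gene sraG. There position 3311288 of the minus strand held 74.8% (74.2 to 75.4) of 21239 untreated and 76.4% (76.0 to 76.8) of 36485 apyrase ends. Small RNA genes were matched by position only, without their strand, so these ends need not belong to the small RNA. Position 3073755, 64 nt upstream of the coding sequence of epd, an erythrose 4-phosphate dehydrogenase, held 95.2% and 96.0%. Between the ribosomal protein genes rplA and rplJ, position 4179665 held 79.7% (79.0 to 80.3) without and 94.7% (94.3 to 95.1) with apyrase. Within the boundaries of the small RNA gene rydC, position 1491442 held 34.3% and 32.8%. Among sites that moved downstream, those with most counts were in dapA, a lysine synthesis gene (2599743 to 2599741), 10 nt upstream of the coding sequence of the transcription factor gene rob (4635322 to 4635320), in exuR, the repressor of hexuronate use (3246670 to 3246673), and in trmJ, a tRNA methyltransferase gene (2663264 to 2663263). At the site of rob, 12.1% of the apyrase ends lay at the untreated top position, which held 36.7% of the untreated ends. In dapA and trmJ the untreated top was not resolved, with 30.7% and 30.6% of untreated ends there against 28.7% and 29.6% at the apyrase top.

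Fewer pause sites were called with apyrase. With the total of both strands outside stable RNA genes equal, 16727460 3′ ends, 29936 sites were called in the untreated and 23718 in the apyrase library. Of these, 13591 were shared at the same nucleotide, which was 45.4% of the untreated and 57.3% of the apyrase sites, against 152 at shifted positions. On the sense strand of protein-coding genes 11895 and 13032 sites were called (7.12 and 7.80 per kb), and on the opposite strand 2709 and 823 (1.62 and 0.493 per kb), but depth per strand differed: the apyrase library had 1.31 times the sense and 0.601 times the opposite-strand counts of the untreated one. With each strand thinned to equal counts, both orders turned, to 11942 and 10334 sense sites and 506 and 979 opposite-strand sites. An apyrase site lay 1 nt upstream of an untreated site 1713 times and 1 nt downstream 858 times. Pairs of sites at neighbouring nucleotides made 3.37% of the untreated and 6.97% of the apyrase sites. The order of the totals turned at a minimum of 50 counts, which left 7577 untreated and 9858 apyrase sites. In simulated libraries with no difference but counting error, 77.2% of 25161 sites were shared.

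Attenuator leader peptides are short coding sequences ahead of the genes they regulate, where polymerase pausing can time the decision to stop or go on. Those listed here lie mostly ahead of amino acid and nucleotide operons. In 8 of the 11 leaders the position with most counts, within the leader and the 100 nt after it, was the same nucleotide in both libraries. In leuL, the leucine operon leader, nucleotide 68 (position 83641) held 41.1% (40.0 to 42.2) of 7870 untreated and 44.6% (43.9 to 45.4) of 16119 apyrase ends. Nucleotide 146 from the start of mgtL, the magnesium transporter leader (position 4467576), held 45.9% (44.9 to 46.9) and 37.0% (36.2 to 37.8), and nucleotide 41 of ivbL, ahead of ilvBN (position 3852948), held 12.6% (11.6 to 13.6) and 19.6% (18.9 to 20.4). The tops of pheL (nucleotide 67), pheM (20), ilvL (16), thrL (69) and pyrL (34) were also shared. In hisL, the histidine leader, the top was nucleotide 122 without apyrase, with 11.5% of ends there against 5.70% with apyrase, and nucleotide 71 with apyrase, with 7.71% against 11.1%. In tnaC, the tryptophanase leader, it was nucleotide 84 (14.1% and 6.25%) without and nucleotide 23 (9.89% and 10.3%) with apyrase. The tops of trpL rested on 11 and 14 counts and had no usable order.

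Per gene, few counts differed 2-fold. Sense 3′ ends were compared in 1987 protein-coding genes after scaling to their sum over genes with an assigned strand, 5973878 and 8344489 before the minimum of 100 counts. At least 2-fold higher with apyrase were 2 genes, yadX (2.29-fold, log2 1.19, interval 1.00 to 1.39) and ivbL (2.01-fold, log2 1.00, 0.95 to 1.06). At least 2-fold lower were 17 genes, led by hofP (3.33-fold, log2 -1.74, -1.92 to -1.55), and cas2, a CRISPR adaptation gene (3.26-fold, log2 -1.70, -1.89 to -1.52). Below them came ykfF (2.54-fold), ydaG (2.49-fold), pyrL, the leader of pyrBI (2.40-fold), yiiF (2.35-fold), yffS (2.25-fold), ygiW (2.17-fold), argF, an ornithine carbamoyltransferase (2.14-fold), hokE, a toxin (2.09-fold), yagB (2.08-fold) and glxK, a glycerate kinase (2.07-fold). In hofP and cas2, 30.1% and 27.9% of the untreated counts lay on the other strand, compared with 19.3% in yadX, 22.4% in mdtU and 3.97% in ivbL. With apyrase that share rose to 37.5% in hofP and rose in cas2 too, whereas it fell in yadX, mdtU and ivbL. In the apyrase library alone, neither hofP nor cas2 met the strand rule. The 12 lowest genes held at most 72.3% of the counts of both libraries on their assigned strand, and the 12 highest at least 88.2%. The strand of the lowest genes is therefore less sure. Behind yadX and ivbL followed hisL (1.99-fold), the toxin peptide genes ibsE (1.83-fold), ibsD (1.82-fold) and ibsA (1.79-fold), mdtU (1.82-fold), yfgG (1.80-fold), tnaC (1.77-fold), ypfM, nlpI, an outer membrane lipoprotein (both 1.72-fold), and ylcH (1.72-fold). The ibs genes resemble each other, and reads could have been split between copies. Their strand was taken from the counts, so these ends may belong to RNA from the strand opposite the toxin coding sequences.

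The ratio went with density: in the tenth of genes with fewest counts per nt the median was 0.720-fold, and in the tenth with most it was 1.2-fold. These medians, log2 -0.47 and 0.26, became -0.11 and 0.02 after the local density of the other strand was subtracted. The median over all genes was log2 -0.13, and 37 genes were at least 1.5-fold higher and 151 at least 1.5-fold lower. Scaling by the median ratio gave 4 higher and 7 lower genes at 2-fold, and the authors' own factors, which add 0.24 to every log2 ratio, gave 13 and 5. Without the top position of each gene 0 genes were 2-fold higher, with yadX at 1.99-fold and ivbL at 1.85-fold, and after the subtraction yadX was at 2.18-fold and ivbL at 1.66-fold. A stricter strand rule of 75% of counts kept 1201 genes, with 1 higher and 0 lower.

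**Figure D2:**
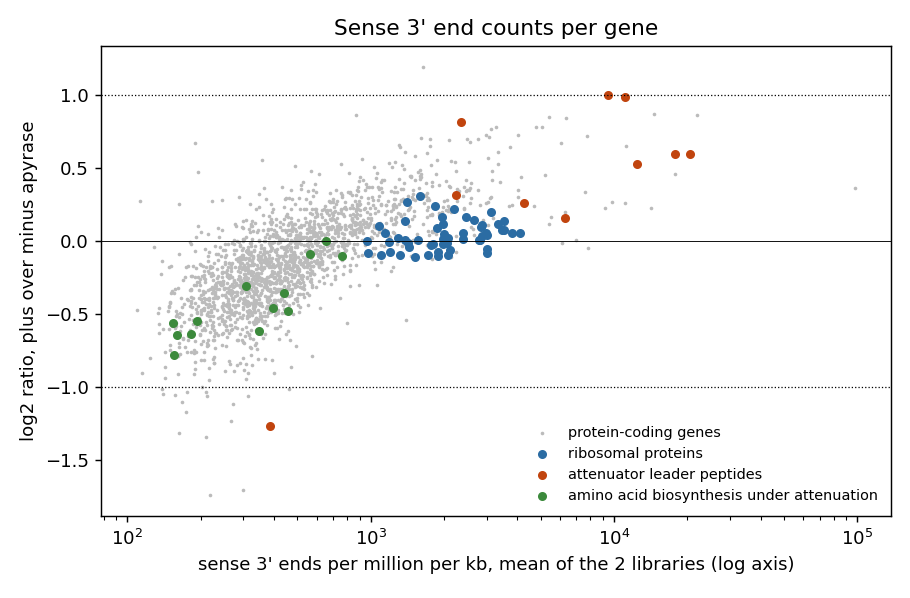
Each point is 1 of 1987 protein-coding genes, with its sense 3′ ends per kb, scaled to a common library total and averaged over the 2 libraries (x axis, log axis) and the log2 ratio of the apyrase over the untreated library (y axis); dotted lines mark 2-fold. Leader peptides (orange) lie mostly above 0 and amino acid biosynthesis genes (green) mostly below; with the authors' factors all points move up by 0.24.

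Gene lists fixed before the data were examined were set against 10000 random lists of the same size and density, as a description of these 2 libraries. Leader peptides were higher with apyrase and the operons behind such leaders lower, and both stood outside the central 95% of random lists. The random lists were matched on density class only, not on gene length or position. They drew genes singly, so percentiles may be too extreme where list members share an operon. Leader peptide genes are short, and whether their ratios come from the higher density near gene starts with apyrase, described below, was not tested. Of 10 measured leader peptides 9 were higher and pyrL was lower, with a median of 1.48-fold (percentile 99.8), and ilvL and leuL, those with most counts, were both 1.51-fold higher. Of 13 measured amino acid biosynthesis genes under attenuation, 12 were lower, with a median of 0.717-fold (percentile 0.48), thrA, an aspartate kinase, at 0.933-fold, ilvB, an acetolactate synthase subunit, at 0.729-fold and hisH at 0.582-fold; with the authors' factors 10 were lower and thrA was higher. The 5 cold shock genes were all higher, also with the authors' factors, with a median of 1.37-fold (percentile 99), led by cspA at 1.65-fold, with cspE at 1.37-fold. The 54 ribosomal protein genes had a median of 1.017-fold, and although 35 were higher, no random list from the same density classes had a median as low (percentile 0). Among them rplE was at 1.04-fold, rpsA at 1.08-fold and rpmA at 1.24-fold. With the authors' factors all 54 were higher, and after subtracting the density of the other strand 49 were lower. That subtraction brought leader peptides to a median of 1.19-fold (log2 0.26, interval of the median -0.13 to 0.69, against 0.56, 0.16 to 0.99, before), with 7 of 10 higher and percentile 98.6. It brought cold shock genes to 1.16-fold (5 of 5 higher, percentile 92.3) and the attenuated operons to 0.856-fold (11 of 13 lower, percentile 2.64).

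The other 13 lists with at least 2 measured genes lay within the central 95% of random lists. After the subtraction pyrimidine synthesis (percentile 0.585) and RNA polymerase and elongation factors (1.41) lay outside it, and without the top position of each gene the SOS genes did (97.7). All 10 TCA cycle genes were lower (median 0.765-fold, percentile 20.1), with acnB at 0.773-fold, icd at 0.919-fold and sdhA at 0.597-fold, but 4 of them, icd included, were higher with the authors' factors. Of 16 heat shock genes 14 were higher (1.10-fold, percentile 7.21; 4 after the subtraction), with the chaperones dnaK at 1.09-fold and groL at 1.03-fold and the sigma factor gene rpoH at 1.23-fold. All 5 outer membrane protein genes were higher (1.08-fold, percentile 13.7) before the subtraction and 0 after it, with ompA at 1.15-fold and lpp at 1.17-fold. The 8 measured SOS genes had a median of 1.08-fold (percentile 96.3), with the repressor gene lexA at 1.36-fold and recA at 1.10-fold, and 4 stationary phase genes 1.06-fold (93.0), with rpoS at 1.13-fold and wrbA at 1.09-fold. Pyrimidine synthesis had 4 of 5 genes lower (0.702-fold, percentile 3.60), with pyrH at 0.702-fold, pyrF at 0.579-fold and pyrG, the CTP synthase gene, at 1.08-fold. Purine synthesis had 3 of 5 lower (0.808-fold, 26.6), with purA at 1.27-fold, guaA at 0.799-fold and guaB at 0.752-fold, and salvage 7 of 9 lower (0.888-fold, 42.7), with cdd at 1.28-fold, udp at 1.06-fold and deoD at 0.703-fold. With the authors' factors pyrimidine synthesis had 3 of 5 and salvage 4 of 9 lower.

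The lists of RNA polymerase and elongation factors, ATP synthase, translation factors and glycolysis had medians near 1 in the main scaling. With the authors' factors they were 1.16-fold for RNA polymerase and elongation factors, 1.21-fold for ATP synthase, 1.23-fold for translation factors and 1.21-fold for glycolysis, and after the subtraction 0.906-fold, 0.995-fold, 0.913-fold and 0.934-fold. In the main scaling the list of RNA polymerase and elongation factors had a median of 0.978-fold (percentile 16.9), with rpoD at 0.980-fold, rpoB at 0.856-fold and greA, a transcript cleavage factor gene, at 0.644-fold. ATP synthase genes had 1.025-fold (5.40), with atpA at 0.934-fold, atpB at 1.12-fold and atpI at 1.22-fold. Translation factors had 1.04-fold (21.5), with fusA at 1.04-fold and prfA at 0.734-fold, while tufA at 1.06-fold is uncertain because tufB is nearly identical to it. Aminoacyl-tRNA synthetases had 0.906-fold (67.0), with serS at 1.41-fold and thrS at 1.16-fold, and 16 of 22 were higher with the authors' factors against 5 in the main scaling. Glycolysis and sugar uptake had 1.03-fold (10.9), with gapA at 1.18-fold, ptsI at 1.13-fold and pgi at 0.815-fold. Of the flagella and chemotaxis list 1 gene was measured, cheW, at 0.496-fold.

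**Figure D3:**
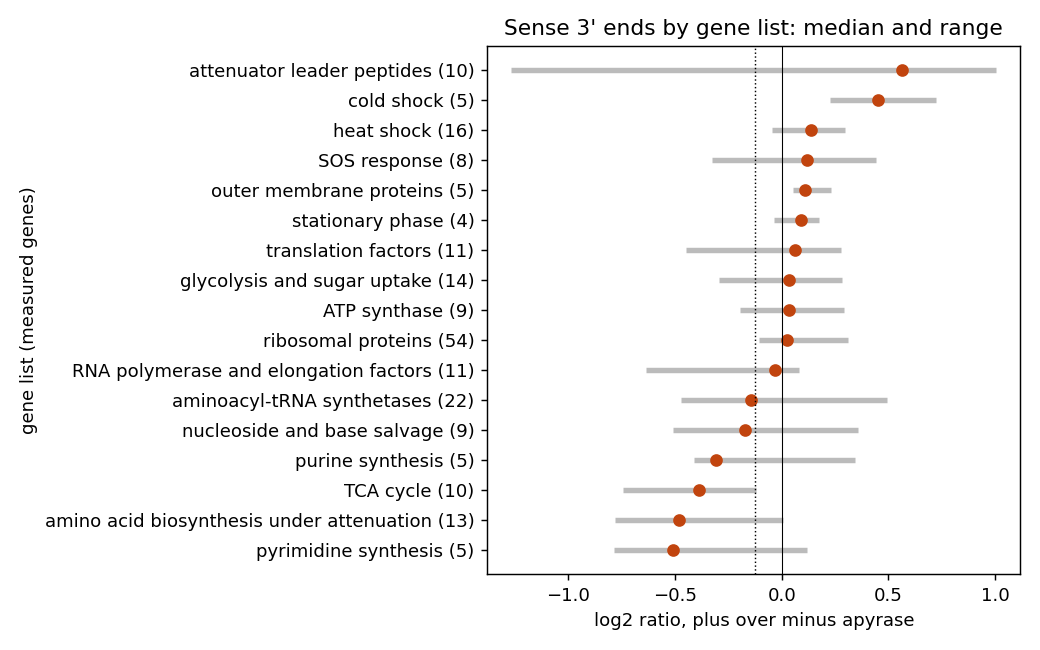
For each fixed gene list (y axis, with its number of measured genes), the median (orange point) and the range (grey bar) of the log2 ratio of the apyrase over the untreated library (x axis); the solid line marks 0 and the dotted line the median of all 1987 genes, -0.13. Leader peptides and cold shock genes have the highest medians, 0.56 and 0.45; the authors' factors move all values up by 0.24.

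Along coding sequences, 3′ ends lay nearer the start with apyrase. In 1348 genes of at least 500 nt, the density of the first 100 nt relative to the whole gene had a median of 1.49 (1.45 to 1.53, resampling genes) in the untreated and 1.73 (1.66 to 1.79) in the apyrase library, and was higher with apyrase in 75.7% of genes. The last 100 nt had 0.799 (0.785 to 0.817) and 0.696 (0.680 to 0.720), higher with apyrase in 26.4%. After subtracting the density of the other strand, the first 100 nt had 1.89 and 1.95, higher with apyrase in 57.9% of 1345 genes, and the last 100 nt had 0.651 and 0.607, higher in 46.0%.

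Stable RNA took a larger share of the library with apyrase, and so did the sense strand of protein-coding genes, from 33.2% without to 42.3% with it. Per 100 such sense ends there were 20.3 stable RNA ends without and 21.3 with apyrase, a ratio of 1.05. Sense 3′ ends in tRNA genes made 6.48% (6.47 to 6.49) of the untreated and 8.65% (8.64 to 8.66) of the apyrase library, and asnW, an asparagine tRNA gene, alone made 0.718% and 0.968%. The transfer-messenger RNA ssrA had 0.151% and 0.243%, the RNase P RNA rnpB 0.0532% and 0.0631%, and the signal recognition particle RNA ffs 0.0315% and 0.0468%. All stable RNA together made 6.72% (6.71 to 6.73) and 9.0% (8.99 to 9.02). Ribosomal RNA genes and ssrS, the 6S RNA gene, held 0 counts in both libraries on stretches that read as masked, so no level can be given for them.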

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

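The tests of *B. subtilis* reads and of transcription after lysis were chosen after the density on the opposite strand was seen. Signal outside the sense strand, which the comparisons of genes do not use, was flagged by a rule that any few counts would meet. No library free of polymerase-held RNA was compared, so the background to be expected is not known. On the strand opposite the 1995 genes with an assigned strand lay 23.7% (23.6 to 23.7) of the untreated and 12.5% (12.4 to 12.5) of the apyrase counts of those genes. Genes of at least 500 nt without an assigned strand, 1817 in number, held 29.4% of all untreated and 18.8% of all apyrase 3′ ends, a median of 2.34 and 1.50 per nt. The median share of their counts on the plus strand of the chromosome was 49.7% in both libraries. This value cannot show whether each gene's counts were even over the strands. Genes with a clear excess on a strand had been assigned and so left out, and genes of both directions were pooled.

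The opposite-strand density without apyrase was 1.57 times that with it, 1.06 against 0.676 raw counts per nt, and 1.86 times with the authors' factors. *B. subtilis* reads placed on the *E. coli* genome would not follow the *E. coli* replication origin, yet the density opposite the assigned genes near the origin was 2.14 (2.04 to 2.21) times that of the farthest such genes without and 1.97 (1.84 to 2.10) times with apyrase. Such a gradient would also come from fragments of *E. coli* DNA. The tests of DNA assume that its ends lay at the same positions in both libraries, which was not checked. Called sites on that strand moved 1 nt upstream 3.39 (2.11 to 5.66) times as often as downstream. Such sites stand above their surroundings by definition, so they say little about even background. Outside called sites, each untreated count was multiplied by the apyrase count 1 nt upstream and by that 1 nt downstream, with counts capped at 10. The upstream products exceeded the downstream ones 1.18 (1.17 to 1.19) times, against 1.00 and 0.992 between parts of 1 library, where random splitting sets about 1. On the sense strand the ratio was 1.06 (1.05 to 1.07). If DNA ends did not move, this argues against DNA as the whole of the opposite-strand signal. DNA may still be part or most of it, since no value here measures its share. How much of the excess without apyrase (1.57) is DNA was not measured and stays open. The excess may also be transcription started or continued after lysis where nucleotides remained. Apyrase and any other difference between the 2 libraries cannot be told apart with 1 library each. Transcription of both strands in the living cells was not tested.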

How the results depend on the processing

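The alternatives with the authors' factors, the 75% strand rule, the subtraction of the other strand, both strands of all genes, the split by strand, the thinning per strand and the other thinning seeds were chosen after seeing the data. No paired analysis was possible because each condition had 1 library. Not run, for want of a genome sequence or of spike-in counts, were the alternatives planned for the spike-in ratio, for scaling by spike-in counts, for bases at pauses and at 3′ ends and for consensus sites. The excess of upstream over downstream register shifts kept its direction in every alternative run, and 8 of 11 leaders had the same top after thinning too. Gene lists outside the central 95% numbered 4 in the main setting and after the subtraction, but cold shock and attenuated operons were then replaced by RNA polymerase and pyrimidine synthesis; without the top positions they numbered 5, with SOS added. The cause of the movements below was not tested unless named. Depth limits single genes and sites: trpL had 11 and 14 counts at its tops.

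Stable RNA counted on both strands made 6.76% and 9.05%. Genes 2-fold higher and lower numbered 4 and 7 with scaling by the median ratio, 13 and 5 with the authors' factors, 1 and 7 with at least 500 counts, 1 and 0 with the 75% strand rule (1201 genes) and 32 and 298 on both strands of all 4272 genes; 0 were higher without the top position of each gene and 4 after subtracting the other strand. Of the genes 2-fold apart in the main scaling, 2 higher and 7 lower genes were among those with the median ratio, 2 and 5 among those with the authors' factors, 1 and 11 among those after the subtraction and 2 and 2 among those on both strands. Along genes, the first 200 nt had 1.31 untreated and 1.51 with apyrase and the last 200 nt 0.835 and 0.735; without the top position the last 100 nt had 0.825 and 0.727; after the subtraction the first 100 nt had 1.89 and 1.95 and the last 0.651 and 0.607.

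Pause sites without and with apyrase numbered 63601 and 35588 at 10 counts, 7577 and 9858 at 50 counts (5224 shared), 11895 and 13032 on the sense strand (7382 shared) and 2709 and 823 on the opposite strand (415 shared). With equal counts per strand they numbered 11942 and 10334 on the sense (6503 shared) and 506 and 979 on the opposite strand (230 shared), so the order of both strand splits turned. Sites at the same nucleotide, upstream and downstream made 92.8%, 5.04% and 2.20% at 6 SD, 91.7%, 5.91% and 2.38% at 100 counts (centroid -0.0547 nt), 87.3%, 7.85% and 4.83% within 5 nt (centroid -0.0543 nt) and 91.1%, 6.04% and 2.82% on the sense strand. Sites called without apyrase alone moved downstream in 2.97% (centroid -0.0714 nt), and of those called with apyrase alone 89.1% were at the same nucleotide and 7.30% upstream (centroid -0.0550 nt). On the opposite strand 4.05% moved downstream (centroid -0.0526 nt). With 5 other thinning seeds the upstream share ranged from 6.84% to 7.03%.

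Ratios near 1 turned. With the median ratio atpA had log2 0.028, thrA 0.027 and icd 0.0057; with the authors' factors rpoB had 0.018, atpA 0.14, thrA 0.14 and icd 0.12; on both strands atpA had 0.17, thrA 0.18 and icd 0.20. With the 75% strand rule rplE had -0.044, udp -0.018, fusA -0.041, tufA -0.018 and groL -0.053. After the subtraction the median of ribosomal proteins was -0.20, with rplE at -0.21 and rpsA at -0.077, and fusA had -0.14, tufA -0.16, dnaK -0.17, groL -0.22, recA -0.042, gapA -0.058, ptsI -0.056, ompA -0.085, lpp -0.081 and thrS -0.00014. Of 70 named genes, the subtraction left 14 within their counting intervals, moved 41 and turned 12, and gave no value for 3.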

Other observations

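The tests of tRNA ends and of single high positions, and the profile at start codons, were chosen after the values were seen. At start codons, where the annotation rather than the counts sets the position, 3′ ends lay more on the first nucleotide and less on the second with apyrase. Averaged over 1909 protein-coding genes and relative to the mean of the 60 nt on each side, the first nucleotide of the coding sequence stood at 1.26 (1.19 to 1.33, resampling genes) without and 2.17 (2.04 to 2.30) with apyrase, a difference of 0.911 (0.810 to 1.018). The second nucleotide stood at 3.31 (3.12 to 3.53) and 2.75 (2.55 to 2.97), a difference of -0.561 (-0.666 to -0.460). Of the ends on these 2 nucleotides the first held 32.7% without and 48.2% with apyrase, and its share was higher with apyrase in 1349 and lower in 417 of 1820 genes. The last nucleotide before the coding sequence had 1.51 in both libraries.

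Pause registers are named in the study's title, and the apyrase step is the explanation that the design gives for the upstream shift. Shortening of all 3′ ends would add to the nucleotide before tRNA ends, and at pause sites that nucleotide gained 3.47 percentage points, yet over 42 tRNA genes the difference was -0.0077 points (-0.060 to 0.041); an exonuclease that spares mature tRNA was not tested. Parts of 1 library differ by random splitting only, so a ratio near 1 was fixed in advance and its interval shows counting spread. The ratio was at most 0.991 between such parts, against 3.91 between libraries at that depth. Variation between library preparations was not covered by this split. The higher background without apyrase should matter least at strong sites, yet at sites with at least 100 counts in each library the ratio was still 4.16 (2.99 to 5.89). What stays open is the apyrase step itself, which 1 library per condition does not separate from any other difference between the libraries.

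The higher density near gene starts with apyrase has a technical explanation that stays open. Single positions with many counts do not carry it, since without the top position of each gene 75.5% of genes were still denser in the first 100 nt. Even background flattens a profile that is high at the start, and the untreated library had more of it. After subtracting the density of the other strand 57.9% of genes were denser, so the background may account for much of the difference, and what remains cannot be told apart from an imperfect subtraction.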
